A study of Homo sapiens with 11 samples.

How the data were processed

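Total RNA of BEAS-2B cells, an established line of human bronchial epithelial cells, was measured on 11 Affymetrix one-colour arrays, 1 array per sample. Per the labels, 3 samples were unstimulated, 3 were exposed to UV-inactivated Pseudomonas aeruginosa, 2 to UV-inactivated Staphylococcus aureus and 3 to respiratory syncytial virus (RSV) at a multiplicity of infection of 1, each pathogen for 4 h. RNA was amplified in 1 round and labelled with biotin, per the labels' protocols.

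The deposited table holds the intensity of 22277 probe sets per array. Per the submitters' processing notes, the authors made these values with RMA in the affy package of R 2.4.0. RMA corrects the background, normalizes between arrays and summarizes the probes of a probe set, so that differences between arrays in overall brightness are removed and changes of dim probe sets are compressed. The values were on a linear scale (8.24 to 12632.17 over the 11 arrays), while the design fixed beforehand had allowed for log2 values, so log2 was taken before every test. Median intensity per array lay between 82.2 and 85.7. Scanner images and detection calls were not used here, so signal over background is unknown. The number of arrays, 2 or 3 per group, limits the precision.

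Probe sets were named through the array annotation, with symbols matched by Entrez number to a current gene table. The match covered 19052 of the 19064 probe sets with 1 gene symbol and changed 0 symbols. Another 1043 probe sets carry several symbols, 2108 have none listed, and 62 are control probe sets. These 3 classes were left out of the gene tests, the first 2 being tested in an alternative over all probe sets. Of the 11963 genes, 4310 have several probe sets, and the probe set with the highest mean over the 11 arrays stood for the gene. The genome build behind the probe design is not given in the sources used here, and no coordinates are printed.

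All 11 arrays entered 1 limma fit (limma 3.58.1, R 4.3.3) with a mean per group, moderated variances (default eBayes, 7 residual and 3.95 prior degrees of freedom) and 6 contrasts: each pathogen against unstimulated, and each pair of pathogens. P-values were adjusted by Benjamini-Hochberg over all genes within a comparison, and genes with adjusted p under 0.05 were counted as changed. Errors of log2 fold changes are limma's standard errors (SE), and fold changes are on the RMA scale. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

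Named genes were chosen by a rule fixed before the data were examined. It takes, in each comparison against unstimulated, the 10 largest rises and 5 largest falls among changed genes whose treated arrays all lie on 1 side of all control arrays. It adds up to 4 members per gene list with the largest change past the test, and 15 fixed genes (CXCL8, CXCL1, CXCL10, CCL20, IL6, CSF2, CSF3, TNFAIP3, NFKBIA, ICAM1, PTGS2, IFNB1, IFIT1, TLR2 and TLR5). Between pathogens it takes the 5 largest differences in each direction, and where fewer than 5 genes pass, the 5 smallest p-values. CSF2 has no probe set with its symbol alone and was not tested.

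The 23 gene lists were also fixed before the data were examined. They cover chemokines; cytokines and colony-stimulating factors; the NF-kB pathway and its feedback regulators; interferon-stimulated genes; interferons, their receptors and regulatory factors; pattern recognition receptors and adaptors; immediate early genes and MAP kinase feedback; adhesion molecules and surface receptors; and antimicrobial, acute phase and mucosal defence. Others cover proteases, prostaglandin synthesis and wound repair, antigen processing and presentation, the unfolded protein response and amino acid stress, heat shock proteins, oxidative stress and metallothioneins, and hypoxia and glycolysis. The rest are cholesterol synthesis, the cell cycle, p53 targets and apoptosis, airway epithelial differentiation, leukocyte, fibroblast and mesenchymal and endothelial markers, and reference genes. Each list was tested with limma's camera (two-sided, preset inter-gene correlation 0.01), adjusted over the 69 tests against unstimulated, beside camera with an estimated correlation and fry. Camera compares a list with all other genes. Fry asks whether a list's genes move, on balance, 1 way, and compares them with no other genes.

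Control probe sets were examined as a check. The poly-A spike-in controls (dap, lys, phe and thr) split the arrays at a mean log2 signal of 7.3 into 4 low arrays (unstimulated 2, P. aeruginosa 3, S. aureus 2 and RSV 3) and 7 high arrays, so every group spans both. This technical batch was added to the fit as a block, and the high arrays were fitted alone, as alternatives chosen after seeing the data. The low arrays number 1 per group and give a value but no test. The high arrays nearest to the split were S. aureus 1 (7.37) and RSV 1 (7.41). Replicate numbers shared between groups were not used as a block, since no label says that they mark a shared culture or day.

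The other alternatives were fixed before the data were examined: quantile normalization, median centring, a filter to the brighter genes, all probe sets, the mean of a gene's probe sets, a variance trend with robust moderation, array weights, a fit of the compared groups alone, the replicate number as a block, stricter thresholds, and leaving out each array in turn. The comparisons against unstimulated share 3 control arrays, and 100 simulations of unchanged groups gave the agreement that shared controls alone produce.

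The fit was tested on simulated data for the 11963 genes with 200 changed genes, divided between changes of 0.5, 1 and 2 log2 units. Against unstimulated, it recovered 53.4%, 90.6% and 99.6% of genes changed by 0.5, 1 and 2 log2 units for P. aeruginosa. It recovered 41.8%, 86.2% and 99.4% for S. aureus, and 55.0%, 94.4% and 99.7% for RSV. False calls made up 4.99%, 5.00% and 5.33% of the calls. The larger changes in a simulation ease the Benjamini-Hochberg threshold, so recovery of changes of 0.5 log2 units can be lower without them. Simulated noise was independent between genes and arrays. In the data, 1 component held 56.1% of the variance within groups, so recovery and the share of false calls may differ there.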

Results

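Gene expression of BEAS-2B bronchial epithelial cells was compared between unstimulated cells (n = 3 arrays) and cells exposed for 4 h to UV-inactivated P. aeruginosa (n = 3), UV-inactivated S. aureus (n = 2) or RSV at a multiplicity of infection of 1 (n = 3). P. aeruginosa is a Gram-negative and S. aureus a Gram-positive bacterium, and RSV is an enveloped RNA virus of the airways. The design asks how the same epithelial cells respond to different airway pathogens. Log2 intensities of array pairs correlated across the 11963 genes with r between 0.98988 and 0.99796 within groups (10 pairs) and between 0.97607 and 0.99753 across groups (45 pairs). Across genes, the first principal component held 50.6% of the variance and the second 21.1%. The first set the RSV arrays (26.8 to 31.9) apart from all others (-14.2 to -7.27). The second differed within groups: replicate 1 arrays (3.39 to 25.4) lay above the low spike-in arrays (-18.4 to -8.12) in every group.

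Control probe sets differed between arrays in ways that the analysis had to follow. The poly-A spike-in signal was low in 1 array of every group and high in the others, so counts of genes are given also with this batch as a block and in the high arrays alone. Signal of the 5' probe set for 28S ribosomal RNA was 11.4 ± 1.39 log2 units in the RSV arrays (SD, n = 3) and 7.85 ± 0.338 in the unstimulated arrays (SD, n = 3), a difference of 3.56. The probe set for the middle of 28S stood at 10.03 ± 0.210 and 8.43 ± 0.307 in these groups, a difference of 1.60. The highest values outside the RSV group were 8.28 and 8.64. The 3' probe set of 28S, which was dim, was not raised in this way: it stood at 5.47 ± 0.211 and 5.26 ± 0.118, a difference of 0.215, and the highest RSV array (5.72) lay below the highest other array (5.73). Signal of the 18S probe sets varied within groups, and for the 3' set it largely followed the spike-in batch. The low spike-in arrays stood at 10.1 (unstimulated), 10.9 (P. aeruginosa), 8.81 (S. aureus) and 9.93 (RSV). The high spike-in arrays stood at 5.93 to 6.87, except RSV array 2 at 10.3. The high arrays alone are therefore not uniform in 18S signal for RSV. For the 5', middle and 3' sets the RSV mean lay 1.24, 0.718 and 1.31 log2 units above the unstimulated mean, with an SD among RSV arrays of 2.39, 1.68 and 1.89, and the highest RSV array stood at 11.0 and 9.35 for the 5' and middle sets against 8.51 and 8.49 elsewhere. The bacteria differed from unstimulated by -0.210 to 0.265.

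**Figure D1:**
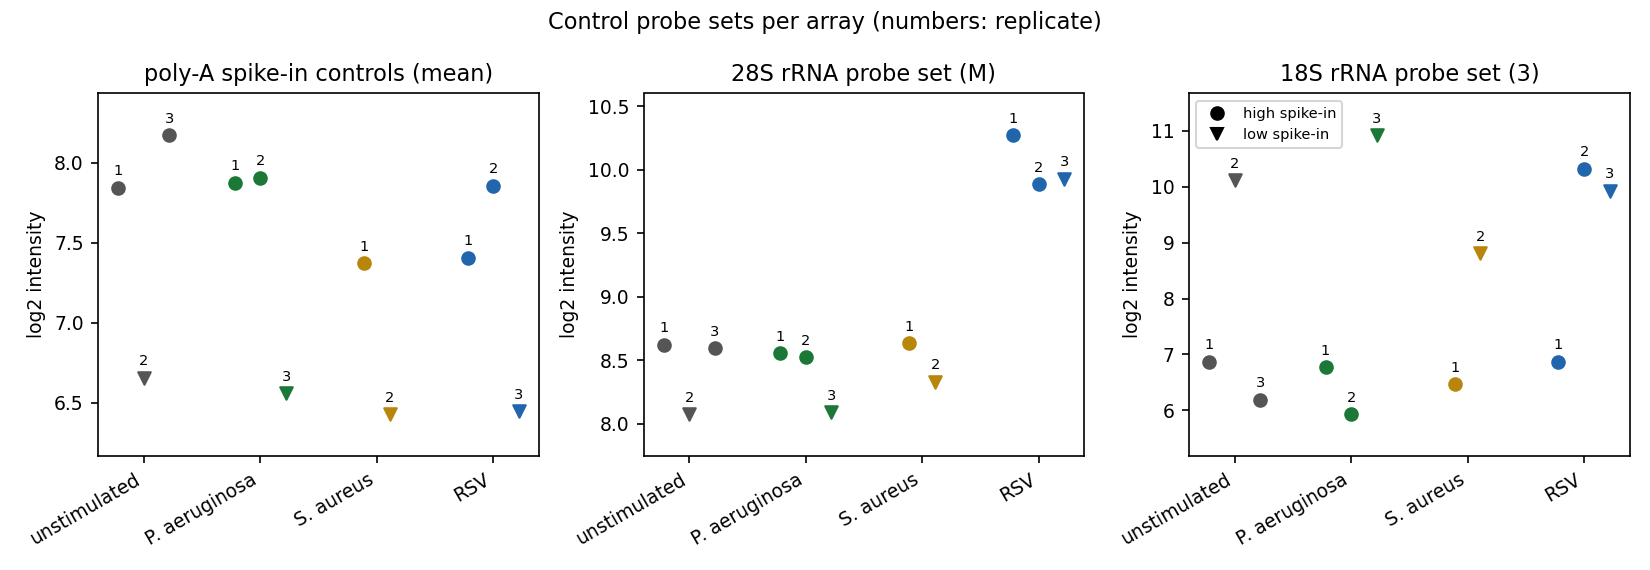
Log2 intensity of the poly-A spike-in controls, of the middle 28S ribosomal RNA probe set and of the 3' 18S ribosomal RNA probe set, 1 point per array with its replicate number; circles are arrays with high and triangles arrays with low spike-in signal. All 3 RSV arrays lie above the highest other array, 8.64, for the middle 28S probe set, while 1 array of each group has low spike-in signal.

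With P. aeruginosa 123 genes rose and 31 fell, and the 5 largest rises were chemokine genes. CXCL8, the main human neutrophil attractant, went from an intensity of 81.9 to 2078, a 25.4-fold rise (log2 4.67 ± 0.125, SE, n = 3 against 3, limma adjusted p = 8.26e-09). CXCL1 rose 13.8-fold, CXCL2 10.5-fold, CCL20 10.2-fold and CCL2, an attractant of monocytes, 8.54-fold. The next largest rises were TNFAIP3, a deubiquitinase that restrains NF-kB (log2 2.51 ± 0.216), MMP12, a macrophage elastase (2.31 ± 0.120), PTX3, a soluble pattern recognition molecule (2.25 ± 0.155), TIPARP (2.18 ± 0.0993) and the transcription factor KLF4 (2.03 ± 0.249). The largest falls were BMP4, a secreted growth factor (log2 -1.57 ± 0.114), the G-protein regulator RGS7 (-1.24 ± 0.143), the vasoactive peptide gene ADM (-1.22 ± 0.161), ZBTB18 (-0.97 ± 0.202) and RGS4 (-0.91 ± 0.165).

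Inflammatory gene groups rose with P. aeruginosa. Among 21 measured chemokines 7 rose and 0 fell (9 rose adjusted over the list alone), with CXCL6 and CXCL3 beside the 5 named above (camera adjusted p = 1.85e-19, and adjusted p = 0.00858 with an estimated correlation). Of 24 cytokine genes 7 rose and 0 fell (8 rose adjusted over the list alone), led by IL6 (log2 1.87 ± 0.106), IL1B (1.67 ± 0.127), IL1A (1.39 ± 0.144) and IL11 (1.09 ± 0.114), with camera adjusted p = 2.12e-12 and adjusted p = 0.0053 with an estimated correlation. In the NF-kB list 11 of 27 rose (17 adjusted over the list alone) and 1, MAP3K14, fell (-0.45), with camera adjusted p = 5.42e-35 and adjusted p = 0.000228 with an estimated correlation. Beside TNFAIP3 its risers included TNFAIP2 (1.995 ± 0.128), the survival gene BCL2A1 (1.48 ± 0.129), RELB (1.04 ± 0.127) and NFKBIA, the NF-kB inhibitor (0.96 ± 0.0849). With the spike-in batch as a block 7, 7 and 14 members of these lists rose, and 6, 5 and 8 did in the high spike-in arrays alone. MAP3K14, CXCL6 and CXCL3 lie outside the rule for named genes and were named after their values were seen.

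Interferon-stimulated genes rose with P. aeruginosa, while none of the 4 measured interferon genes of the preset lists passed the test. Of 44 members 12 rose and 0 fell (23 rose adjusted over the list alone), with camera adjusted p = 1.07e-36 and adjusted p = 0.00246 with an estimated correlation. MX1, an antiviral GTPase, rose 2.60-fold (log2 1.38 ± 0.138), IFIT1 2.17-fold (1.12 ± 0.117), RIGI, a cytosolic RNA sensor, 2.15-fold (1.10 ± 0.108) and OAS1 2.09-fold (1.06 ± 0.137). IFNB1 changed by log2 0.02 ± 0.138 at an intensity near 20 (19.9 against 19.6) and CXCL10 by -0.02 ± 0.0721 at 19.8 against 20.1. The other measured interferon genes of the preset list, named after their values were seen, were IFNA1 (-0.135), IFNA2 (0.035) and IFNG (0.0753), each with adjusted p = 0.998. Interferon genes outside the list were not examined. The list also names the interferon genes IFNE, IFNL1, IFNL2 and IFNL3 and the receptor gene IFNLR1. These were not measured, so whether they changed is unknown. Of the 14 measured interferons, receptors and regulatory factors, IRF1 (0.77 ± 0.105) and IFNGR1 (0.60 ± 0.0867) rose, 2 members also when adjusted over the list alone (camera adjusted p = 0.0055, and adjusted p = 0.0890 with an estimated correlation). Under a block for the spike-in batch 16 interferon-stimulated genes rose. In the high spike-in arrays alone 5 rose, and the calls of IFIT1 (1.08, adjusted p = 0.0587), IRF1 (0.79, adjusted p = 0.118) and IFNGR1 (0.55, adjusted p = 0.0974) were lost. Without unstimulated array 3 the list of interferons and receptors did not pass camera (adjusted p = 0.0527).

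Some surface, matrix and defence genes also rose with P. aeruginosa. In the adhesion and receptor list 4 of 34 members rose (7 adjusted over the list alone): ICAM1 (log2 1.88 ± 0.104), TNFRSF9 (1.79 ± 0.104), VCAM1 (1.64 ± 0.115) and CD83 (0.75 ± 0.107). TNFRSF21 fell (-0.43), and camera gave adjusted p = 1.91e-08, and adjusted p = 0.00444 with an estimated correlation. Of 38 protease, prostaglandin and repair genes 7 rose and 0 fell (11 rose and 2 fell adjusted over the list alone), among them the matrix metalloproteinases MMP12, MMP1 (1.79 ± 0.137) and MMP3 (1.53 ± 0.160) and the urokinase gene PLAU (0.66 ± 0.113), with camera adjusted p = 3.5e-06 and adjusted p = 0.0143 with an estimated correlation. PTGS2, the inducible cyclooxygenase, gave -0.02 ± 0.0931 at an intensity of 12.6 against 12.8. PTX3 and the complement genes C3 (1.32 ± 0.164) and CFB (1.17 ± 0.116) were the 3 of 32 defence genes that rose, and 3 rose adjusted over the list alone. The median of that list was -0.01 and its mean 0.15 (camera adjusted p = 0.0119, and adjusted p = 0.540 with an estimated correlation). Another probe set of CFB gave -0.15. The defence list did not pass without unstimulated array 2 (adjusted p = 0.137) or P. aeruginosa array 1 (0.122), nor the protease list among brighter genes (0.0558). PLAU lost its call in the high spike-in arrays (0.0587) and without unstimulated array 2 or 3 or P. aeruginosa array 1 or 2 (up to 0.0864). With the spike-in batch as a block 5, 8 and 3 members of these lists rose, and in the high arrays alone 4, 3 and 3.

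Few members of the other lists passed the test with P. aeruginosa. Of 18 cholesterol synthesis genes 2 fell, MSMO1 (log2 -0.50 ± 0.0839) and HMGCS1 (-0.57 ± 0.115), and 7 fell adjusted over the list alone (camera adjusted p = 2.17e-09, and adjusted p = 0.00444 with an estimated correlation). Among 39 immediate early genes 4 rose (KLF4, IER3 at 1.01 ± 0.0796, MAFF at 0.91 ± 0.151 and JUNB at 0.65) and 2 fell (CCN2 at -0.71 ± 0.111 and DUSP1 at -0.58), against 9 and 4 adjusted over the list alone (camera adjusted p = 0.000679, and adjusted p = 0.405 with an estimated correlation). SLC7A11, the cystine transporter (0.79 ± 0.102), was the riser among 25 unfolded protein response genes, with 2 adjusted over the list alone (camera adjusted p = 0.00234, and adjusted p = 0.0803 with an estimated correlation). TAP1 (0.58 ± 0.104) was the riser among 21 antigen presentation genes, alone also when adjusted over the list alone (camera adjusted p = 0.0221, and adjusted p = 0.405 with an estimated correlation). Of 27 oxidative stress genes 0 passed, and 1 rose adjusted over the list alone (camera adjusted p = 0.000858, and adjusted p = 0.258 with an estimated correlation). With the block 4 cholesterol genes fell, and 5 immediate early genes rose and 4 fell. The block also gave 3 unfolded protein response genes and 1 oxidative stress gene that rose. In the high spike-in arrays 0 cholesterol genes fell, 2 immediate early genes rose and 0 fell, and SLC7A11 and TAP1 did not pass. The antigen presentation list did not pass camera without unstimulated array 3 (adjusted p = 0.338) or P. aeruginosa array 1 (0.0954) or 3 (0.158). JUNB, DUSP1 and, among the surface receptors, TNFRSF21 were named after their values were seen.

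The remaining lists were not shifted past camera's test by P. aeruginosa. Fry, which compares a list with no other genes, passed hypoxia and glycolysis (adjusted p = 0.00646), fibroblast (0.0299) and cell cycle genes (0.0311). RIPK2 (log2 0.46 ± 0.0973) rose among 33 pattern recognition genes (camera adjusted p = 0.278), while TLR2 (0.01 ± 0.102, intensity 27.1 against 26.9) and TLR5 (0.11 ± 0.111, 18.4 against 17.1) did not pass. ADM was the member that fell among 29 hypoxia and glycolysis genes (camera adjusted p = 0.237). PMAIP1 (0.46 ± 0.0855) rose and BCL2L1 (-0.44 ± 0.0849) fell among 24 p53 and apoptosis genes (camera adjusted p = 0.140), and CLDN1, a tight junction protein (1.20 ± 0.148), rose among 29 airway epithelial genes (camera adjusted p = 0.695). Of 18 heat shock genes (camera adjusted p = 0.691), 40 cell cycle genes (0.282), 26 leukocyte (0.358), 23 fibroblast (0.344) and 13 endothelial markers (0.360) and 11 reference genes (0.691), 0 passed the gene test. Adjusted over the list alone, the calls in these lists were the same in number, except 3 rises and 2 falls in the p53 list and 1 fall among reference genes. CSF3 gave -0.05 ± 0.188 and was not past the test. Of 13 lists past camera with P. aeruginosa, 7 hold with an estimated correlation: chemokines, cytokines, NF-kB, interferon-stimulated, adhesion, protease and cholesterol genes.

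In total 154 of 11963 genes passed limma's test against unstimulated at adjusted p under 0.05, 42 rising and 3 falling at least 2-fold. An unadjusted p under 0.05, which a share of 0.05 of unchanged genes has on average, was found for 691. Under a block for the spike-in batch 225 genes passed, and 59 in the high arrays alone, where KLF4 (adjusted p = 0.0698), CLDN1 (0.0698), SLC7A11 (0.0892) and CCN2 (0.0549) lost their calls. The count fell to 91, 97 and 97 without unstimulated arrays 1, 2 and 3, and to 101 and 95 without P. aeruginosa arrays 1 and 2. Falls dropped further in proportion: against 31 in all, there were 8, 12 and 8 without unstimulated arrays 1, 2 and 3, 6, 12 and 12 without P. aeruginosa arrays 1, 2 and 3, and 4 in the high spike-in arrays, against 66 with the block. Leaving out an array ended the calls of ZBTB18, HMGCS1 and TAP1 for each of the 6 arrays (adjusted p up to 0.229, 0.170 and 0.112). For P. aeruginosa array 1 or 2 it ended the call of MAFF (0.0641 and 0.0728). RIPK2 lost its call without any of 5 arrays, unstimulated 1, 2 or 3 or P. aeruginosa 1 or 2 (up to 0.242), MSMO1 without the same 5 (up to 0.0794), and BCL2L1 without unstimulated 1 or 2 or any P. aeruginosa array (up to 0.167). RGS4 (up to 0.112) and PMAIP1 (up to 0.127) lost theirs without unstimulated 1 or 3 or P. aeruginosa 1 or 3. In the high spike-in arrays HMGCS1 (0.712), BCL2L1 (0.466), PMAIP1 (0.208), RGS4 (0.199), RIPK2 (0.129), TAP1 (0.106), MSMO1 (0.104) and ZBTB18 (0.101) did not pass either. The mean of a gene's probe sets ended the calls of HMGCS1 (0.932), BCL2L1 (0.900), ZBTB18 (0.532) and PMAIP1 (0.0882), and quantile normalization (0.0754) or median centring (0.0842) that of RIPK2.

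S. aureus changed 0 genes past the test, and its median log2 change at the 123 genes that P. aeruginosa raised was -0.0025. CXCL8 had an intensity of 113 against 81.9 (log2 0.47 ± 0.140, SE, n = 2 against 3, limma adjusted p = 0.657), with 0.19 in the high and 0.86 in the low spike-in arrays. IL6 differed by 0.08 ± 0.119, CXCL1 by 0.0016 ± 0.129, CCL20 by -0.20 ± 0.151, ICAM1 by -0.01 ± 0.116, NFKBIA by 0.10 ± 0.0949, TNFAIP3 by -0.25 ± 0.241 and IFIT1 by -0.33 ± 0.131. TLR2, a receptor for Gram-positive lipoproteins, was at 29.3 against 26.9 (0.13 ± 0.114), and TLR5 (0.32 ± 0.124), IFNB1 (0.26 ± 0.154), CSF3 (0.22 ± 0.210), PTGS2 (-0.06 ± 0.104) and CXCL10 (-0.12 ± 0.0806) did not pass either. The 5 smallest p-values belonged to CYP1B1, a cytochrome P450 that metabolizes aromatic compounds (0.63 ± 0.0859, adjusted p = 0.187), CLIC3 (-0.65 ± 0.113), SPRR2B (0.60 ± 0.111), MPI (-0.54 ± 0.10) and STC2 (0.63 ± 0.116), the last 4 with adjusted p = 0.453. CYP1B1 was the 1 gene that passed under the variance trend with robust moderation. It also rose with P. aeruginosa (log2 1.97, limma adjusted p = 1.58e-07).

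In every one of the 23 lists 0 members passed with S. aureus over all genes tested. Adjusted over the list alone, 1 gene rose and 1 fell among pattern recognition genes, and 1 rose in each of the immediate early and oxidative stress lists. Cholesterol synthesis genes were shifted downwards as a group (median log2 -0.15, camera adjusted p = 0.000944, and adjusted p = 0.0312 with an estimated correlation). Interferon-stimulated genes leaned down (median -0.11, adjusted p = 0.0263) and leukocyte markers up (median 0.17, adjusted p = 1.47e-06). Neither shift passed with an estimated correlation (adjusted p = 0.375 and adjusted p = 0.405 with an estimated correlation). Among brighter genes neither passed camera (0.118 and 0.637). Without S. aureus array 1 neither passed either (0.0530 and 0.237), nor did the interferon-stimulated list without S. aureus array 2 (0.179) or unstimulated array 1 (0.0546). At an unadjusted p under 0.05 limma listed 844 of 11963 genes, and the smallest adjusted p was 0.187. A share of 0.05 of unchanged genes falls under that bound on average, so many of the 844 can be chance. Half-widths of the 95% confidence intervals had a median of 0.273 log2 units. On simulated data the test found 41.8% of changes of 0.5 log2 units, so changes of that size could be missed. Those simulations also held changes of 1 and 2 log2 units, which ease the Benjamini-Hochberg threshold. With 0 genes past the test here, the share found may be lower. The simulated noise was also independent between genes and arrays, unlike the deviations in these data. The count was 0 with the spike-in batch as a block. It was also 0 in the high spike-in arrays alone, which hold 1 S. aureus array and take the spread from the other groups.

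RSV gave the broadest response, led by heat shock and immediate early genes. HSPA6, a stress-inducible chaperone, went from an intensity of 44.4 to 4081, a 92.0-fold rise (log2 6.52 ± 0.107, SE, n = 3 against 3, limma adjusted p = 4.05e-11). The orphan nuclear receptors NR4A3 (53.2-fold), NR4A1 (20.7-fold) and NR4A2 (20.2-fold), the transcription factors FOSB (33.2-fold), ATF3 (24.2-fold) and FOS (23.6-fold) and the kinase SIK1 (19.4-fold) followed. CXCL8 rose 20.2-fold (4.34 ± 0.125) and CXCL2 19.0-fold (4.25 ± 0.172). The largest falls were the phosphatase PTPRE (-1.81 ± 0.166), the exchange factor TRIO (-1.53 ± 0.126), the helicase BRIP1 (-1.50 ± 0.399), the membrane-bound protease MMP16 (-1.49 ± 0.158) and the transcription factor GLI2 (-1.48 ± 0.285). Other probe sets differed for TRIO (up to 0.28 over 7 probe sets), GLI2 (0.02) and MMP16 (up to -0.05 over 4).

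**Figure D2:**
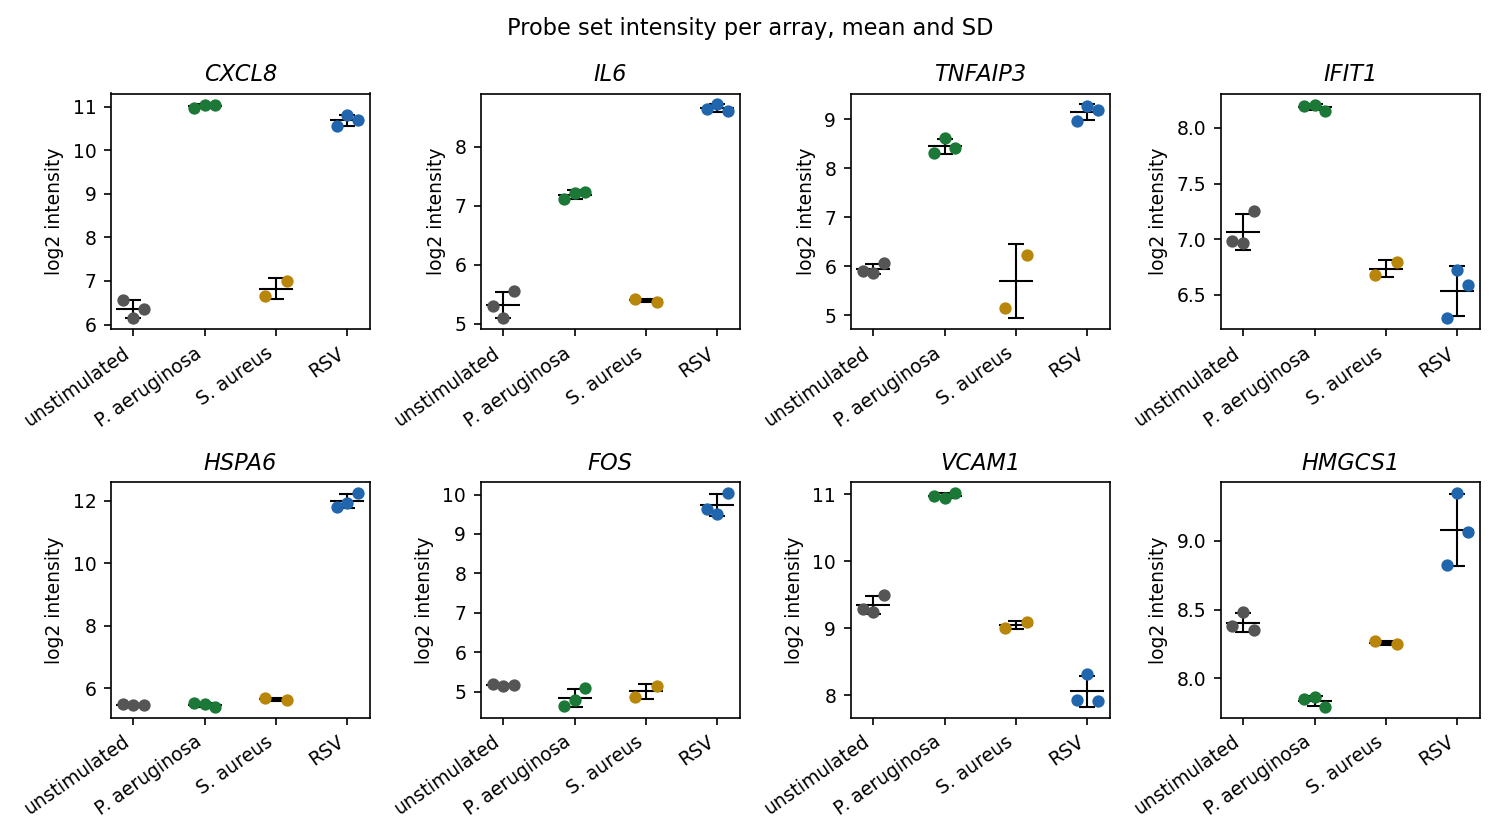
Log2 intensity of 8 genes per array in the 4 groups; points are arrays, dashes group means and bars SD. CXCL8 stands at similar heights with P. aeruginosa (2078) and RSV (1653), HSPA6 and FOS are high in the RSV arrays, and IFIT1 and VCAM1 are highest with P. aeruginosa.

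Of 39 measured immediate early genes 38 rose with RSV and 0 fell, 38 also when adjusted over the list alone, with a median log2 change of 1.72 (camera adjusted p = 4.79e-55, and adjusted p = 0.0053 with an estimated correlation). The exception, DUSP2, was at 0.15 and was named after its value was seen. Of 18 heat shock genes 15 rose and 0 fell (16 rose adjusted over the list alone), with a median of 1.31 (camera adjusted p = 4.97e-20, and adjusted p = 0.0279 with an estimated correlation). HSPA6, the co-chaperone DNAJB1 (2.91 ± 0.0792) and the small heat shock proteins CRYAB (2.73 ± 0.200) and HSPB8 (2.44 ± 0.123) led this group. With the spike-in batch as a block 38 and 16 members rose, and in the high arrays alone 38 and 13. In the same RSV arrays the 5' and middle 28S probe sets stood 3.56 and 1.60 log2 units above the unstimulated arrays, and the 3' set 0.215.

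Chemokine and cytokine genes rose with RSV too. Of 21 chemokines 6 rose and 0 fell, 6 also when adjusted over the list alone, with CXCL1 at 17.8-fold (log2 4.16 ± 0.116) and CCL20 at 4.53-fold (2.18 ± 0.135). Camera gave adjusted p = 2.41e-06, and adjusted p = 0.0890 with an estimated correlation. Of 24 cytokine genes 5 rose and 0 fell, 5 also when adjusted over the list alone: IL6 (3.34 ± 0.106), LIF (2.32 ± 0.117), IL11 (1.999 ± 0.114), IL32 (0.55 ± 0.137) and IL12A (0.37). Camera gave adjusted p = 0.000679 for this list, and adjusted p = 0.0766 with an estimated correlation. In the NF-kB list 9 of 27 rose and 3 fell, the same numbers as adjusted over the list alone, with TNFAIP3 (3.21 ± 0.216), the kinase MAP3K8 (2.09 ± 0.255), NFKBIA (1.59 ± 0.0849) and REL (1.54 ± 0.227) leading (camera adjusted p = 0.00617, and adjusted p = 0.0668 with an estimated correlation). The 3 that fell were TRAF3 (-0.91), MAP3K14 (-0.37) and TNIP2 (-0.25), named with IL12A after their values were seen. CXCL10 (-0.08 ± 0.0721), CSF3 (0.12 ± 0.188) and PTGS2 (-0.07 ± 0.0931) did not pass. Under a block for the spike-in batch 6, 5 and 11 members rose, in the high arrays alone 6, 4 and 9, and the 5' and middle 28S signal was raised in these arrays. IL32 lost its call in the high arrays (adjusted p = 0.0743), without unstimulated array 3 (0.0756) and without RSV array 3 (0.0771).

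Interferon-stimulated genes did not rise as a group with RSV at 4 h. Of 44 members 2 rose and 4 fell, also when adjusted over the list alone (median -0.0035, mean -0.04, camera leaning up with adjusted p = 0.909). IRF9 (log2 0.71 ± 0.112) and IRF7 (0.59 ± 0.0955) rose, while IFI44 (-0.84 ± 0.186), RIGI (-0.80 ± 0.108), TRIM21 (-0.56) and IFIT1 (-0.53 ± 0.117) fell. IFNB1 gave 0.05 ± 0.138 at an intensity of 20.3 against 19.6. The raised 5' and middle 28S signal was present in these arrays too. Among 14 interferons, receptors and regulatory factors IRF1 (1.80 ± 0.105) and IRF8 (0.91 ± 0.221) rose and IFNAR2 (-0.40 ± 0.0971) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.247). Of 33 pattern recognition genes 4 rose, among them TLR4 (1.08 ± 0.293), CD14 (0.68 ± 0.105) and TICAM1 (0.49 ± 0.0799), and 4 fell, among them the signalling adaptor MAVS (-0.66 ± 0.160), against 4 and 5 adjusted over the list alone (camera adjusted p = 0.970). The others were NOD1 (0.33), TBK1 (-0.40), IRAK1 (-0.39) and IL1R1 (-0.32), named like TRIM21 after their values were seen. TLR2 (-0.01 ± 0.102) and TLR5 (0.09 ± 0.111) did not pass. With the spike-in batch as a block 5 interferon-stimulated genes rose and 7 fell, and in the high arrays alone 3 rose and 2 fell, IFIT1 losing its call (-0.61, adjusted p = 0.0573). IRF8 lost its call without unstimulated array 2 (0.0570) or 3 (0.0554), IFNAR2 in the high arrays (0.117), with quantile normalization (0.0638) and without unstimulated 3 (0.0697) or RSV 3 (0.0700). TLR4 lost its call without unstimulated 1 (0.0878) or 3 (0.0880) or RSV 3 (0.10), and MAVS without unstimulated 3 (0.0717) or RSV 1 (0.0511) or 2 (0.0541).

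Metabolic and repair genes made up another part of the RSV response. Of 18 cholesterol synthesis genes 11 rose and 0 fell, 11 also when adjusted over the list alone, with INSIG1 (log2 1.00 ± 0.151), HMGCS1 (0.67 ± 0.115), MSMO1 (0.64 ± 0.0839) and LSS (0.57 ± 0.0896) in front (camera adjusted p = 1.35e-07, and adjusted p = 0.0053 with an estimated correlation). Among 38 protease, prostaglandin and repair genes 15 rose and 1, VEGFC (-0.39), fell (17 rose and 1 fell adjusted over the list alone). MMP3 (3.11 ± 0.160), the activin subunit INHBA (2.39 ± 0.117), endothelin EDN1 (2.19 ± 0.167) and STC1 (1.84 ± 0.130) led them (camera adjusted p = 9.58e-09, and adjusted p = 0.00557 with an estimated correlation). Of 29 hypoxia and glycolysis genes 7 rose and 0 fell (11 rose and 1 fell adjusted over the list alone), including PFKFB3 (1.45 ± 0.0929), NDRG1 (1.14 ± 0.105), SLC2A3 (0.83 ± 0.0873) and MXI1 (0.67 ± 0.137), with camera adjusted p = 0.00317 and adjusted p = 0.0353 with an estimated correlation. Of 24 p53 and apoptosis genes 10 rose and 0 fell (12 rose and 3 fell adjusted over the list alone), among them PMAIP1 (1.25 ± 0.0855), which promotes apoptosis, and MCL1 (1.16 ± 0.0797), which restrains it, with BIK (1.01 ± 0.160) and PLK3 (0.99 ± 0.101). Camera gave adjusted p = 0.000679 for this list, and adjusted p = 0.0353 with an estimated correlation. Under a block for the spike-in batch 11, 18, 11 and 12 members of these lists rose, in the high arrays alone 9, 13, 7 and 9, and the 5' and middle 28S signal was raised in the same arrays. With the mean of a gene's probe sets HMGCS1 (adjusted p = 0.515) and LSS (0.101) lost their calls. VEGFC was named after its value was seen.

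Stress and surface genes moved in both directions with RSV, while the defence genes past the test rose. Of 25 unfolded protein response genes 9 rose, including CEBPB (log2 1.43 ± 0.0781), DDIT3 (1.20 ± 0.209) and DNAJB9 (1.14 ± 0.153), and 3 fell: SLC7A11 (-1.16 ± 0.102), PSAT1 (-0.55) and ASNS (-0.39). The counts adjusted over the list alone were the same (camera adjusted p = 0.110). HMOX1, the inducible heme oxygenase, rose 9.43-fold (3.24 ± 0.305) among 27 oxidative stress genes, of which MT1M (0.53 ± 0.136), SQSTM1 (0.43 ± 0.0957) and AKR1C1 (0.33) also rose and GPX1 (-0.48 ± 0.142) fell, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.0312, and adjusted p = 0.415 with an estimated correlation). In the adhesion and receptor list 6 of 34 rose, among them ICAM1 (1.31 ± 0.104) and CD83 (1.19 ± 0.107), and 4 fell: VCAM1 (-1.29 ± 0.115), CD58 (-1.11 ± 0.0807), IL7R (-1.09) and CD44 (-0.58), with 7 and 4 adjusted over the list alone (camera adjusted p = 0.256). Of 32 defence genes PTX3 (1.58 ± 0.155), C1R (0.56 ± 0.122), CFB (0.41 ± 0.116), C1S (0.37 ± 0.0853) and SLPI (0.36) rose, 5 also when adjusted over the list alone (camera adjusted p = 0.00589, and adjusted p = 0.506 with an estimated correlation). With the spike-in batch as a block 9, 8, 7 and 6 members of these 4 lists rose, in the high arrays alone 6, 2, 5 and 2, where SQSTM1 (0.0849), GPX1 (0.0694), CFB (0.0766) and C1S (0.110) lost their calls. The oxidative stress list did not pass camera without unstimulated array 2 (0.0717) or RSV array 1 (0.0845). GPX1 lost its call with quantile normalization (0.0644), with median centring (0.0663) and without any of 5 arrays, unstimulated 1, 2 or 3 or RSV 2 or 3 (up to 0.142). MT1M lost its call without unstimulated 2 or 3 or RSV 1 or 2 (up to 0.0759), and CFB with the mean of its probe sets (0.134) and without unstimulated 1 or 3 or RSV 2 or 3 (up to 0.105). PSAT1, ASNS, AKR1C1, IL7R, CD44 and SLPI were named after their values were seen, and the 5' and middle 28S signal was raised in the same arrays.

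Most cell cycle genes past the test with RSV fell, and marker genes went both ways. Of 40 cell cycle genes 9 fell, including the centromere genes CENPA (log2 -0.69 ± 0.116) and CENPE (-0.68 ± 0.115) and the cyclin CCNA2 (-0.60 ± 0.138), and 2 rose, CCNE1 (0.88 ± 0.0991) and CDC25A (0.46), against 10 and 2 adjusted over the list alone (camera adjusted p = 0.105). KRT16 (0.57 ± 0.130) rose and KRT7 (-0.75 ± 0.104) fell among 29 airway epithelial genes (camera adjusted p = 0.247). SNAI2 (2.26 ± 0.143), TWIST1 (0.76 ± 0.150) and PDGFRB (0.32) rose and TAGLN (-0.63 ± 0.0818), COL6A3 (-0.39 ± 0.111), POSTN (-0.33) and THY1 (-0.31) fell among 23 fibroblast and mesenchymal markers (camera adjusted p = 0.860). VWF (0.32 ± 0.0923) rose and FLT1 (-0.52 ± 0.115) fell among 13 endothelial markers (camera adjusted p = 0.937), TBP (-0.53 ± 0.122) fell among 11 reference genes (0.887), and 0 of 21 antigen presentation genes passed (0.314). Of 26 leukocyte markers 0 passed while the list leaned up (median 0.11, camera adjusted p = 0.0268, and adjusted p = 0.705 with an estimated correlation). Among brighter genes this list leaned down (adjusted p = 0.689), and without unstimulated array 2 (0.122) or RSV array 1 (0.171) it did not pass. With the spike-in block 13 cell cycle genes fell and 2 rose, and 3 airway epithelial genes rose and 1 fell. The block also gave 2 antigen presentation genes that fell and 2 leukocyte markers that rose. In the high arrays 5 cell cycle genes fell and 2 rose, while 2 fibroblast markers rose and 1 fell. Adjusted over the list alone, the main counts of the airway epithelial, fibroblast, endothelial, reference, antigen presentation and leukocyte lists were the same. CCNA2 lost its call in the high spike-in arrays (adjusted p = 0.0548), FLT1 with the mean of its probe sets (0.109), and KRT16 (0.0514) and TBP (0.0519) without unstimulated array 3. COL6A3 lost its call in the high arrays (0.153), with median centring (0.0589) and without unstimulated 1, 2 or 3 or RSV 1 or 3 (up to 0.132), and VWF in the high arrays (0.078), with quantile normalization (0.0928) and without unstimulated 1 or 3 or RSV 1 or 3 (up to 0.134). CDC25A, PDGFRB, POSTN and THY1 were named after their values were seen, and the 5' and middle 28S signal was raised in the same arrays.

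**Figure D3:**
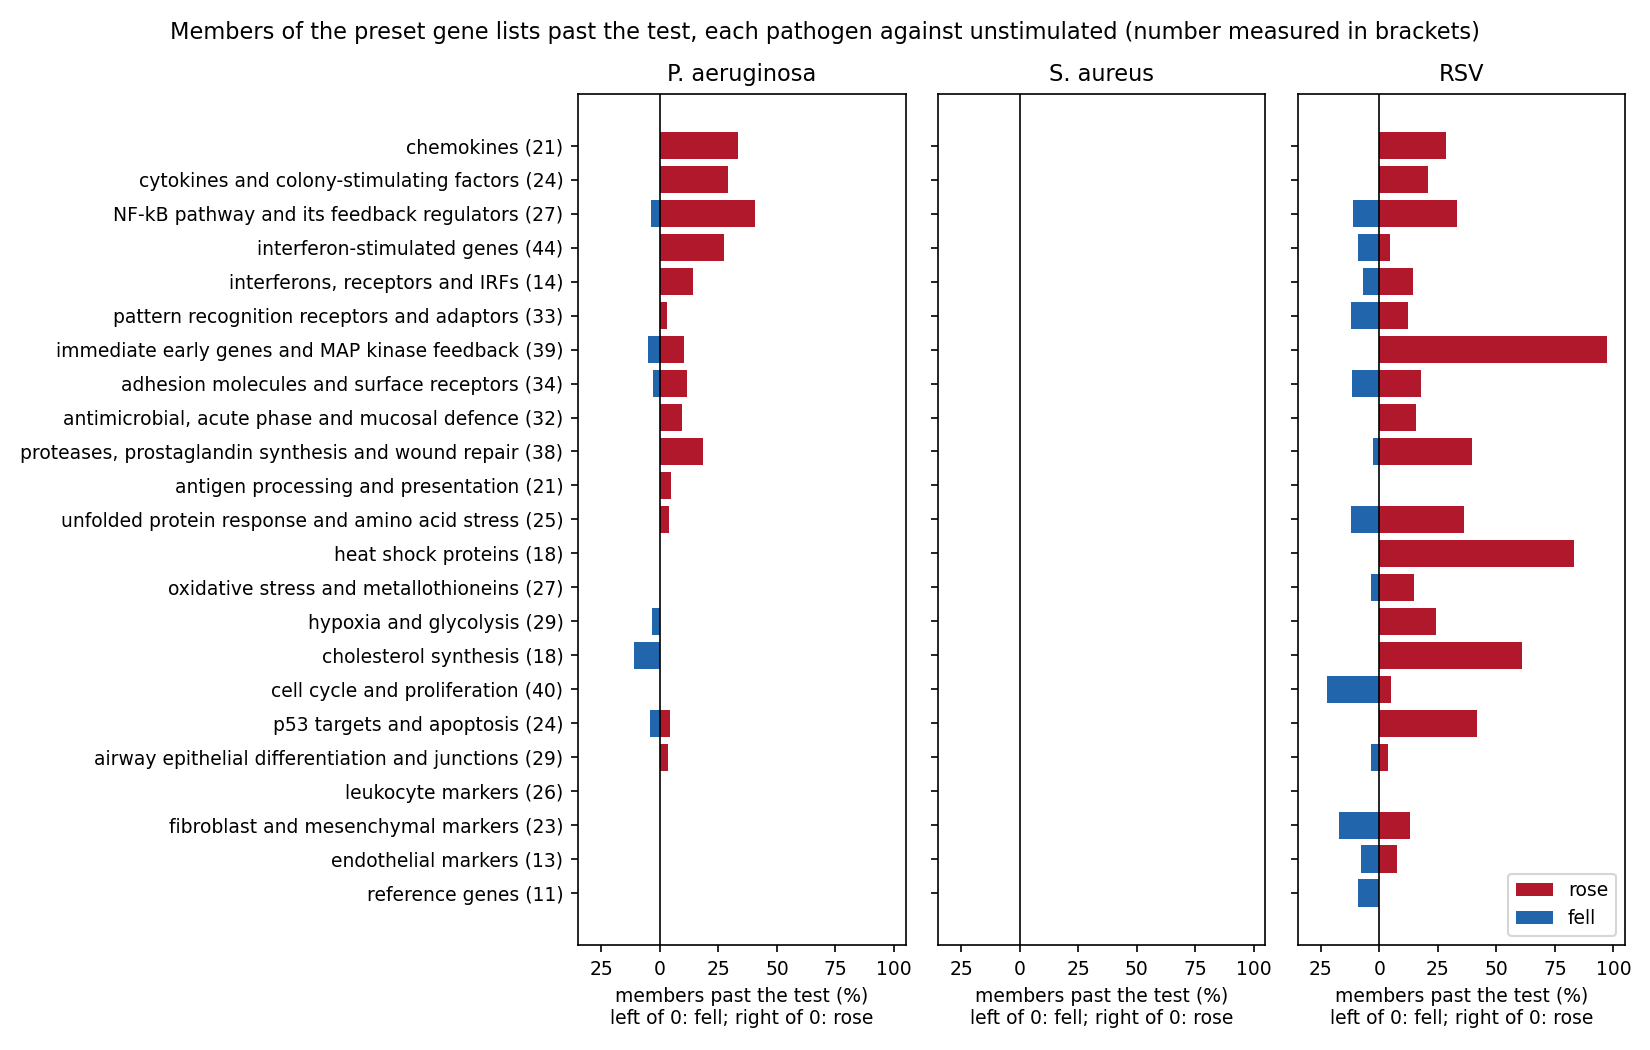
Percentage of the measured members of each of the 23 gene lists that rose (right of 0) or fell (left of 0) past limma's test against unstimulated, with the number of measured members in brackets. Immediate early genes (38 of 39) and heat shock proteins (15 of 18) stand out with RSV, interferon-stimulated genes (12 of 44) rise with P. aeruginosa, and S. aureus has 0 members past the test.

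Over all genes 2094 of 11963 passed limma's test with RSV, 731 rising and 1363 falling, and 3483 had an unadjusted p under 0.05. The excess of falls depended on the normalization: 822 rose and 1041 fell with quantile normalization, and 740 and 1133 with median centring. At least 2-fold, 209 rose and 68 fell. The median change over all genes was -0.01 log2 units, and the 5' and middle 28S signal was raised in all 3 RSV arrays (by 3.56 and 1.60 on average). Of 12 lists past camera with RSV, 6 hold with an estimated correlation: immediate early, heat shock, protease, hypoxia, cholesterol and p53 genes. A block for the spike-in batch gave 3059, and 1387 in the high arrays alone, where 829 fell. Falls numbered 817 without unstimulated array 3 and 883 without RSV array 3. BRIP1 lost its call without unstimulated array 2 (adjusted p = 0.0863) or 3 (0.0655) or RSV array 1 (0.0882). No group received a virus-free preparation of the inoculum, so the comparison is of RSV exposure with no stimulation.

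Set directly against each other, the bacteria differed in the genes that P. aeruginosa had raised. CXCL8 was 18.3-fold higher with P. aeruginosa than with S. aureus (log2 4.20 ± 0.140, SE, n = 3 against 2, limma adjusted p = 5.63e-08), CXCL1 13.8-fold, CXCL2 12.6-fold, CCL20 11.7-fold and CCL2 9.82-fold. BMP4 (-1.48 ± 0.128), ADM (-1.08 ± 0.180), RGS4 (-0.96 ± 0.184), RGS7 (-0.96 ± 0.160) and CCN2 (-0.80 ± 0.124) were lower. Of 44 interferon-stimulated genes 13 were higher and 0 lower (29 higher adjusted over the list alone; camera adjusted p = 5.73e-31, and adjusted p = 0.00217 with an estimated correlation), a list test on direct comparisons that was chosen after seeing the data. With the spike-in block 18 were higher, and in the high arrays alone 5. For the cholesterol list the difference between the bacteria did not pass (camera adjusted p = 0.0751). At the 123 genes that rose with P. aeruginosa the median log2 change was 0.83 with P. aeruginosa and -0.0025 with S. aureus, and 100 of them passed the direct test. At the 31 that fell, the medians were -0.56 and -0.10, and 11 passed. The genes were chosen by the same P. aeruginosa arrays, which favours a large median and a high count in the direct test, while the S. aureus medians share the control arrays with that choice.

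In all 134 genes differed between the bacteria, 120 higher and 14 lower with P. aeruginosa, of which 48 and 2 by at least 2-fold. The spike-in block gave 215, and 51 in the high arrays alone, where S. aureus has 1 array, assumed to vary like the other groups. The count was 84, 82 and 89 without P. aeruginosa arrays 1, 2 and 3, and 68 without S. aureus array 1. Genes lower with P. aeruginosa, 14 in all, numbered 6, 10 and 7 without P. aeruginosa arrays 1, 2 and 3, 6 and 29 without S. aureus arrays 1 and 2, 2 in the high arrays and 46 with the block. RGS4 lost its call without any of these 5 arrays (adjusted p up to 0.250) and with the replicate block (0.0604), RGS7 without P. aeruginosa 2 (0.0529) or 3 (0.0578) or S. aureus 2 (0.0824), ADM without S. aureus 1 (0.168) and CCN2 without S. aureus 2 (0.0548). In the high arrays alone RGS4 (0.255), RGS7 (0.284) and CCN2 (0.141) did not pass.

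P. aeruginosa and RSV differed most in heat shock and immediate early genes. HSPA6 was lower with P. aeruginosa by log2 -6.52 ± 0.107 (SE, n = 3 against 3, limma adjusted p = 4.10e-11), FOSB by -5.00 ± 0.108, NR4A3 by -4.99 ± 0.200, FOS by -4.89 ± 0.149 and NR4A2 by -4.30 ± 0.149. Higher with P. aeruginosa were VCAM1 (7.58-fold, 2.92 ± 0.115), PTPRE (4.61-fold), the retinoic acid enzyme ALDH1A3 (4.58-fold), CYP1B1 (4.57-fold) and SLC7A11 (3.87-fold). In the list tests added for direct comparisons, 37 of 39 immediate early genes (camera adjusted p = 1.59e-53, and adjusted p = 0.00464 with an estimated correlation), 15 of 18 heat shock genes (7e-21, and adjusted p = 0.0199 with an estimated correlation) and 14 of 18 cholesterol genes (5.48e-13, and adjusted p = 0.0019 with an estimated correlation) were lower with P. aeruginosa. Adjusted over the list alone these were 38, 16 and 15. Of 44 interferon-stimulated genes 19 were higher with P. aeruginosa and 0 lower, 23 and 1 adjusted over the list alone (1.09e-09, and adjusted p = 0.0199 with an estimated correlation). Under the spike-in block these 4 lists had 38, 15 and 15 lower and 24 higher, and in the high arrays alone 37, 12 and 10 lower and 14 higher. In all 1879 genes differed, 1167 higher and 712 lower with P. aeruginosa, with 97 and 201 by at least 2-fold. Quantile normalization gave 982 higher and 779 lower. Blocking on the spike-in batch gave 2774, and the high arrays alone 1073, with 593 higher. Higher genes numbered 742 without P. aeruginosa array 2 and 759 without RSV array 3, and the RSV arrays carried the raised 5' and middle 28S signal.

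S. aureus and RSV differed in 1258 genes, 609 higher and 649 lower with S. aureus, and at least 2-fold in 38 and 236. The largest differences were HSPA6 (log2 -6.35 ± 0.120, SE, n = 2 against 3, limma adjusted p = 1.27e-10), NR4A3 (-5.27 ± 0.223), ATF3 (-4.86 ± 0.0946), FOSB (-4.83 ± 0.121) and FOS (-4.72 ± 0.167). Higher with S. aureus were PTPRE (1.65 ± 0.185), ZFHX4 (1.59 ± 0.160), TRIO (1.54 ± 0.141), ZNF767P (1.47 ± 0.125) and LRP8, a lipoprotein receptor (1.43 ± 0.167). Of 39 immediate early genes 38 were lower (camera adjusted p = 5.98e-67, and adjusted p = 0.0032 with an estimated correlation), as were 14 of 18 heat shock genes (1.36e-24, and adjusted p = 0.0148 with an estimated correlation) and 12 of 18 cholesterol genes (3.7e-13, and adjusted p = 0.0019 with an estimated correlation). Adjusted over the list alone these were 38, 15 and 12, with the spike-in block 38, 15 and 13, and in the high arrays, with 1 S. aureus array, 36, 11 and 6, and the RSV arrays carried the raised 5' and middle 28S signal. Blocking on the spike-in batch gave 1903, with 1059 higher, and the high arrays alone 680, with 214 higher. Higher genes numbered 403 without S. aureus array 1 and 397 without RSV array 3. TRIO lost its call with the mean of its probe sets (adjusted p = 0.0704).

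The responses to P. aeruginosa and RSV shared 69 genes that rose and 6 that fell in both, where independent lists of these sizes would share 7.52 and 3.53. In simulations of unchanged groups against the same controls 0 genes were shared, which says nothing about real lists because groups without changes should give hardly any calls. Another 11 genes rose with P. aeruginosa and fell with RSV, and 18 fell with P. aeruginosa and rose with RSV, against 14.0 and 1.89 for independent lists. Log2 changes correlated across genes, which are not independent replicates, with r = 0.305, while unchanged groups gave 0.501 in simulation. Their covariance was 0.0224 and the simulated one 0.00852, a difference of 0.0138. For P. aeruginosa and S. aureus r was 0.222 (simulated 0.449) and the covariance difference -0.00175, and for S. aureus and RSV r was 0.285 (simulated 0.448) and the difference 0.0106. The simulated noise was independent between genes and arrays, so the simulated values leave out deviations that real arrays share. The 3 control arrays cannot be split, so part of the agreement may come from the shared controls. The 75 shared calls became 48 without unstimulated array 1 and 35 in the high spike-in arrays alone, against 112 with the batch as a block. Shared falls, 6 in all, numbered 1, 4 and 1 without unstimulated arrays 1, 2 and 3, 1, 2 and 3 without P. aeruginosa arrays 1, 2 and 3, 1 in the high arrays and 16 with the block.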

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

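In this part the splits of the arrays were chosen before their result was seen, and the other tests after.

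Several genes past the test against unstimulated went up with 1 pathogen and down with the other, against the same controls. The direct difference adds the 2 changes, so that it passes limma's threshold follows from the choice of these genes and is no further evidence. The log2 difference P. aeruginosa minus RSV was 2.92 for VCAM1, 1.95 for SLC7A11, 1.90 for RIGI and 1.65 for IFIT1. It was -2.07 for CCN2, -1.86 for ADM, -1.24 for HMGCS1 and -1.14 for MSMO1. The cholesterol synthesis list, chosen likewise, differed with camera adjusted p = 5.48e-13. The calls of HMGCS1 and MSMO1 with P. aeruginosa rest on arrays named in the report.

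Heat shock and immediate early genes rose with RSV in 53 of 57 measured members, with a median log2 change of 1.53. The spike-in batch is argued against, since 51 members rose in the high spike-in arrays alone. The reference genes had a median of 0.0050. RMA had already normalized the arrays, which largely fixed that value in advance, so it cannot test a scaling of the RSV arrays. Ribosomal RNA carry-over or RNA damage in the RSV arrays cannot be told apart from exposure to RSV, because every RSV array had raised 5' and middle 28S signal. The median rise was 1.44 in the RSV array with the least 5' 28S signal and 1.55 and 1.77 in the others, a ratio of 0.868 to their mean, but that array had the most middle and 3' signal of the 3, and 3 arrays are too few to decide. A stress of the cells by the virus or by its preparation may explain the pattern, and no mock preparation was among the groups to test which.

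Signal of 28S ribosomal RNA probe sets, which enter no gene test, was above the unstimulated arrays by 3.56 (5' set) and 1.60 (middle set) log2 units with RSV, while the dim 3' set differed by 0.215. The spike-in batch is argued against, since for the middle set the lowest RSV array exceeded the highest other array by 1.25 in 1 batch and 1.60 in the other. Brighter hybridization or scanning is argued against as well, since the hybridization controls differed by -0.264 ± 0.290 (SE). Whether the RSV arrays held more ribosomal RNA after priming or RNA cut at new sites was not tested.

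With S. aureus 0 genes passed limma's test (844 at an unadjusted p under 0.05, many of which can be chance, and 1 with a variance trend and robust moderation). A spread between spike-in batches that all groups share is argued against, since 0 genes passed with the batch as a block. A spread between the 2 S. aureus arrays that the block does not remove stays open. On the first component of deviations from group means they lay at -17.2 and 17.2, the other arrays between -14.2 and 14.6. They also had the lowest array weights (0.504 each). Too few S. aureus arrays for changes as large as those with P. aeruginosa is argued against, for the fit that gave 0, by the 134 genes that passed between the bacteria with the same 2 arrays (68 without S. aureus array 1). A fit of these groups alone, with fewer arrays for the spread, gave 44, below the bound set for this test, so for that fit the explanation stays open. Smaller changes stay open, as does a low potency of the inactivated bacteria, which may account for the count and was not tested. Of simulated changes of 0.5 log2 units 41.8% were recovered, among larger ones that ease the adjusted threshold. That share may be too high for these data, and it was found with noise independent between genes and arrays.

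The 6 arrays of a comparison of 3 against 3 can be split in 10 ways, too few for a share under 0.05. The real split, 1 of 10, gave 154 genes for P. aeruginosa against unstimulated, 2094 for RSV against unstimulated and 1879 for P. aeruginosa against RSV, and the highest count of any other split was 0 in each. Every other split mixes arrays of both groups, which widens the spread of the genes that differ. Low counts there follow in part from this construction.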

How the results depend on the processing

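Of the alternatives here, the spike-in block and the high spike-in arrays alone were chosen after seeing the data. The count of genes changed by S. aureus was 0 under every alternative run except the variance trend with robust moderation (1). With all probe sets, RSV against unstimulated gave 3225 and P. aeruginosa against RSV 2846, from more units tested. Array weights gave 239 for P. aeruginosa, 80 between the bacteria and 3185 for P. aeruginosa against RSV. The compared groups alone gave 44 between the bacteria and 594 for S. aureus against RSV, with fewer arrays. In the order P. aeruginosa, RSV, P. aeruginosa against S. aureus, P. aeruginosa against RSV and S. aureus against RSV, adjusted p under 0.01 gave 86, 1155, 70, 1083 and 712. A change of at least 2-fold gave 45, 277, 50, 298 and 274, and the high spike-in arrays alone, which are fewer, 59, 1387, 51, 1073 and 680. Calls shared by P. aeruginosa and RSV went from 75 to 19 at 2-fold and 35 in the high arrays. The spike-in block gave 215 between the bacteria and 1903 for S. aureus against RSV. Leaving out 1 array gave 91 to 105 for P. aeruginosa, 1401 to 2015 for RSV, 68 to 135 between the bacteria, 1307 to 1939 for P. aeruginosa against RSV, 917 to 1181 for S. aureus against RSV and 48 to 71 shared calls, the last over unstimulated, P. aeruginosa and RSV arrays. Where no construction is named, the cause was not tested.

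The share of rises went from 79.9% to 93.2% for P. aeruginosa and from 48.4% to 31.5% for S. aureus against RSV in the high arrays, and from 89.6% to 78.6% between the bacteria with the spike-in block. With quantile normalization it went from 34.9% to 44.1% for RSV and from 62.1% to 55.8% for P. aeruginosa against RSV. Lists past the test numbered 28, 14 with an estimated correlation and 25 with fry, 18 of them among the 28. Fry alone passed hypoxia, fibroblast and cell cycle genes with P. aeruginosa and hypoxia genes with S. aureus (fry adjusted p = 0.0102). With RSV it alone passed cell cycle (0.000158), unfolded protein response (0.00342) and interferon and receptor genes (0.0102). The RSV chemokine (1.57e-05), cytokine (7.12e-05) and NF-kB lists (4.07e-05) passed fry but not camera with an estimated correlation. The leukocyte list with RSV turned direction among brighter genes only (adjusted p = 0.689). Calls of named genes were lost in 96 cases with 1 array left out, 29 in the high arrays, 9 with the mean of probe sets, 4 with quantile normalization and 3 with median centring, and none turned direction.

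Replicate numbers were not taken to pair the arrays, since not every pair with the same number deviated together. Deviations of the 15 same-number pairs had a median correlation of 0.520 (lowest -0.505, 10 over 0.1), those of 30 other pairs -0.323 (10 over 0.1), and 5 of 11 arrays correlated best with their own number. The 6 pairs of replicate 1 arrays gave 0.525 to 0.724. These arrays all had high spike-in signal, and pairs within a spike-in batch had a median of 0.442 against -0.423 across batches. Replicate 1 arrays paired with the other high arrays gave only -0.406 to 0.423. The split into low and high arrays therefore does not account for the agreement of the replicate 1 arrays, and the spike-in block leaves it in the fit. Deviations from a group mean cancel within the group, and those of the S. aureus arrays are exact opposites. The correlations are therefore not independent, and part of each contrast between medians is arithmetic. With the replicate number as a block the counts were 178 for P. aeruginosa, 0 for S. aureus, 2594 for RSV, 143, 2320 and 1488 between pathogens and 87 shared, and 1 named call was lost. Signal over background is unknown, which limits what can be said of dim genes.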

Other observations

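The tests in this part were all chosen after the results were seen. Genes called in opposite directions included several regulators. DUSP1, a phosphatase that switches off MAP kinases, was at log2 -0.58 with P. aeruginosa and 1.93 with RSV (difference -2.51). The differentiation inhibitor ID2 (-0.57 and 1.95), the kinase NUAK1 (-0.61 and 1.84), TUFT1 (-0.69 and 1.54), DLC1 (-0.44 and 1.10) and the neurotrophin BDNF (-0.57 and 0.85) went the same ways. ALDH1A3 (1.42 and -0.77) and TMEM156 (1.12 and -0.55) went the opposite way.

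Among genes whose symbol starts with ZNF, which mark zinc finger proteins, 44 of 235 fell with RSV (18.7%), against 1319 of 11728 other genes (11.2%). The odds ratio was 1.82 (Fisher's exact test, two-sided p = 0.000826, which treats genes as independent). The share that rose was 5.53% against 6.12% (odds ratio 0.898, Fisher's exact test, two-sided p = 0.890).

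TIPARP (log2 2.18 ± 0.0993) and CYP1B1 (1.97 ± 0.0768) rose with P. aeruginosa (SE, n = 3 against 3, limma). Both are textbook targets of the aryl hydrocarbon receptor, a sensor of aromatic compounds, so a rise of its targets as a group may be the reason. The other 4 measured targets had a median of 0.0783 and did not pass the test: CYP1A1 (0.33, adjusted p = 0.472), NQO1 (0.12), ALDH3A1 (0.04) and CYP1A2 (-0.02). With 4 genes, of which NQO1 alone was bright, this neither bears out nor excludes the hypothesis. CYP1B1 leaned up with S. aureus too (log2 0.63, limma adjusted p = 0.187), not past the test.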
